A study of Homo sapiens with 16 samples.

How the data were processed

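Gene expression was measured by sequencing poly(A)-enriched mRNA of HaCaT keratinocytes in 16 libraries. There were 4 groups of 4 libraries, unexposed control cells and cells exposed to fluoxetine at 0.5 µg/L, each collected at 6 h and at 36 h, and the poly(A) enrichment is stated in the labels' protocol. Groups, times and replicate numbers were taken from the sample labels. The authors' file names give the late time as 48 h where the labels say 36 h, and the label was used.

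The authors deposited a whole-number read count per gene and library, not normalized, for 58735 genes together. The authors' table also holds FPKM values, which per the file headers belong to the same libraries. They were computed on a library total that differs from the plain sum of counts, and they entered no test. The genome build is hg38, per the submitters' processing notes. Aligner, counting tool, annotation release and strand setting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies could not be told apart. All 58735 gene identifiers were found in GENCODE release 29 with the same start and end, and 58708 with the same symbol. The other 27 symbols had been turned into dates in the table. Coordinates are those of the deposited table. The table has 24 columns of values that belong to no sample of this series, and these were not used. The authors also deposited a table for each of 4 comparisons with log2 fold changes, per the file headers, and with an unadjusted and an adjusted p-value, per the file headers. The tool behind these tables is not given in the sources used here, and their counts of calls are printed only where the authors' deposited table is named.

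Total counts ran from 15858578 to 30877903 per library. Group means ± SD, in megacounts, were 20.2 ± 1.7 in control and 22.9 ± 5.96 in exposed cells at 6 h, and 18.7 ± 2.62 and 19.7 ± 1.88 at 36 h. A count of 0 allows up to 3 counts, or 0.0972 to 0.189 CPM in these libraries. No pair of replicates agreed within sampling noise, as the smallest chi-square per gene between replicates was 3.282.

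Genes with low counts were removed with filterByExpr, which left 15627 genes. Counts were scaled by TMM and all 16 libraries were fitted together with edgeR's robust quasi-likelihood model, with 12 residual degrees of freedom and a median of 3.21 prior degrees of freedom. The contrasts were fluoxetine against control at 6 h and at 36 h, 36 h against 6 h in control and in exposed cells, and the difference between the exposure effects. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM on TMM-scaled library sizes, and log2 CPM used a prior count of 2. Confidence intervals are at 95%. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (version 1.17.8) were used.

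Of 38 gene lists written for keratinocytes, growth, migration, stress and the known actions of fluoxetine, 34 had at least 5 tested members and were tested with camera at a preset correlation of 0.01. The marker lists of fibroblasts, melanocytes, immune cells and endothelial cells had fewer and are given as summed CPM. Melanocyte markers summed to 4.58 ± 1.8 CPM in control and 4.97 ± 1.63 CPM in exposed cells at 6 h and to 5.62 ± 1.93 and 6.02 ± 0.636 CPM at 36 h. Immune markers summed to 7.54 ± 1.8, 6.48 ± 0.907, 11.8 ± 2.53 and 12.4 ± 3.45 CPM in the same order.

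Named genes followed a rule. Among genes past the threshold with a symbol, a protein-coding biotype and a mean of at least 5 CPM over the libraries, the 10 with the largest log2 fold change in each direction were named. Where fewer than 5 passed in a direction, the 5 with the smallest p were named and described as not past the threshold. For each list that passed, the 4 members with the smallest p were considered, and SLC6A4, MKI67, KRT14, KRT10, IVL, KRT6A, HMGCS1 and SQSTM1 were followed in every comparison. A few items that the rule would name are not reported here. The groups, contrasts, tests, gene lists, naming rule and the first set of other settings were fixed before the data were examined.

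These other settings were RLE and upper-quartile scaling, no filter, a filter of 5 CPM in 4 libraries, DESeq2, limma-voom, a fit of only the 8 libraries compared, the replicate number as a block, a minimum of 1.5-fold, protein-coding genes only, camera with an estimated correlation, fry, and leaving out each library in turn. A plan for files without counts was not needed. Settings added after seeing the data left out 2 or 3 libraries that stand apart, added a term for replicates 1 and 2 against 3 and 4 at 6 h, tested within those replicates, used sample quality weights, and joined the block to the fit of 8 libraries.

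Whether replicate numbers pair the libraries was checked by the correlation of same-numbered libraries' deviations from their group means. At 6 h these were 0.422, 0.256, 0.455 and 0.181 for replicates 1 to 4, all over 0.1, which met the rule used. Control replicates 1, 2, 3 and 4 correlated best with fluoxetine replicates 2, 2, 4 and 3. A difference between replicates 1 and 2 and replicates 3 and 4 would give this too, so pairing by single number was not shown. The labels do not say what a shared number stands for. At 36 h and between times the numbers did not pair the libraries.

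The gene tests were tested on simulated counts drawn from these libraries' means, sizes and gene-wise spread (dispersion), with 15421 genes tested. The simulated counts varied independently between libraries and genes. The replicate differences and the libraries that stand apart entered only through that spread, not as changes that genes share. The shares recovered may therefore be too high or too low for the real data. For fluoxetine at 6 h, 5.97% of 67 genes changed 1.5-fold, 29.9% of 67 changed 2-fold and 69.7% of 66 changed 4-fold were recovered. At 36 h these were 4.48%, 41.8% and 74.2%.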

Results

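HaCaT cells, a spontaneously immortalised line of human epidermal keratinocytes, were left unexposed or exposed to fluoxetine at 0.5 µg/L. Fluoxetine is an antidepressant that blocks the serotonin transporter, the product of SLC6A4. The stated purpose was to find molecular changes behind faster growth and scratch closure at concentrations found in the environment. RNA was collected at 6 h and at 36 h, with 4 libraries in each of the 4 groups, and poly(A)-enriched mRNA was sequenced. The total count per library ran from 15858578 in control replicate 1 at 36 h to 30877903 in fluoxetine replicate 3 at 6 h. After the filter on low counts, 15627 genes were tested. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Genes with near-identical copies, among them KRT6A, KRT6B, SPRR2A, histone and ribosomal protein genes, can share reads, so their levels are uncertain. Levels are in CPM, counts scaled to library size, as mean ± SD over the 4 libraries of a group, and log2 fold changes carry their standard error (SE).

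Time separated the libraries most. The first principal component held 59.2% of the variance and parted 6 h from 36 h, and exposed and control libraries of the same time overlapped on it. The second component held 21% and set control replicate 1 at 36 h apart. In that library ribosomal protein genes took 17.1% of the counts, against 7.52% to 8.27% in control replicates 2 to 4 of the same time, and genes longer than 6000 bases took 24.9%, against 37.3% to 39.5%. Control replicate 4 at 6 h also had a high ribosomal protein share, 10.4% against 5.61% to 7.53% in its group. Fluoxetine replicate 3 at 36 h held 85.7 CPM of summed fibroblast markers, against 38.8 to 41.8 CPM in its group. At 6 h the mean log2 CPM of interferon-stimulated genes was 4.99 to 5.11 in control replicate 1 and in fluoxetine replicates 1 and 2, 6.37 in control replicate 2, and 7.08 to 7.20 in replicates 3 and 4 of both treatments. Each comparison was therefore also made without 3 libraries that stand apart, control replicate 1 at 36 h, control replicate 4 at 6 h and fluoxetine replicate 3 at 36 h, an alternative chosen after seeing the data.

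**Figure D1:**
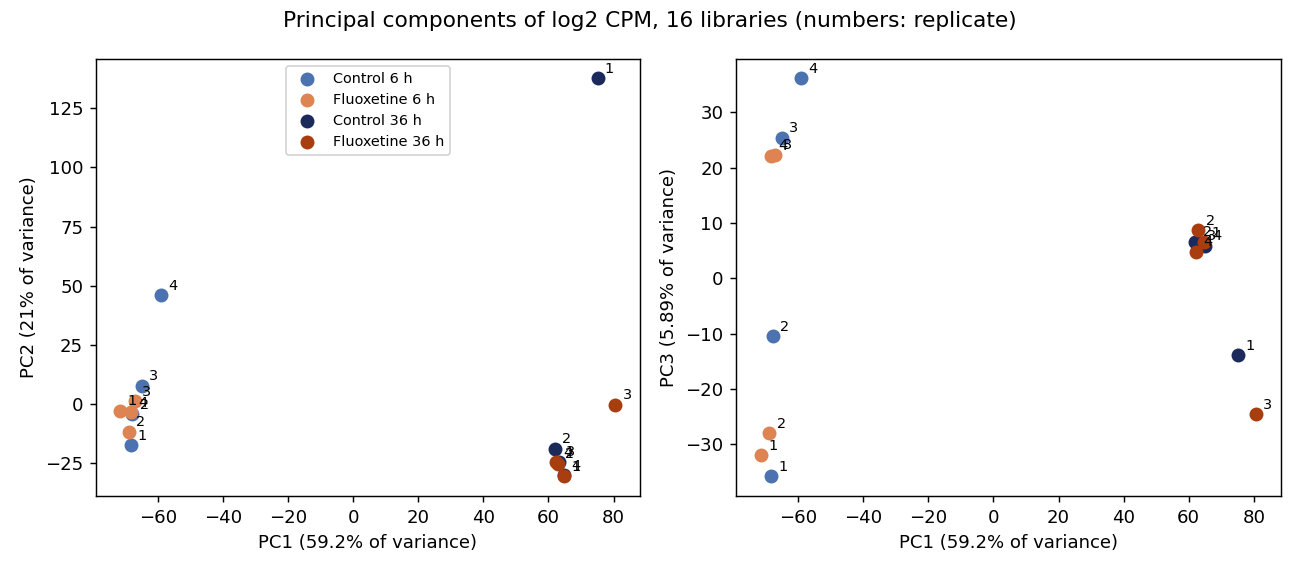
Principal components of log2 CPM for the 16 libraries, coloured by group and numbered by replicate, with component 1 (59.2% of variance) on both horizontal axes and components 2 (21%) and 3 (5.89%) on the vertical axes. Component 1 parts 6 h from 36 h, and control replicate 1 at 36 h lies alone on component 2.

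**Figure D2:**
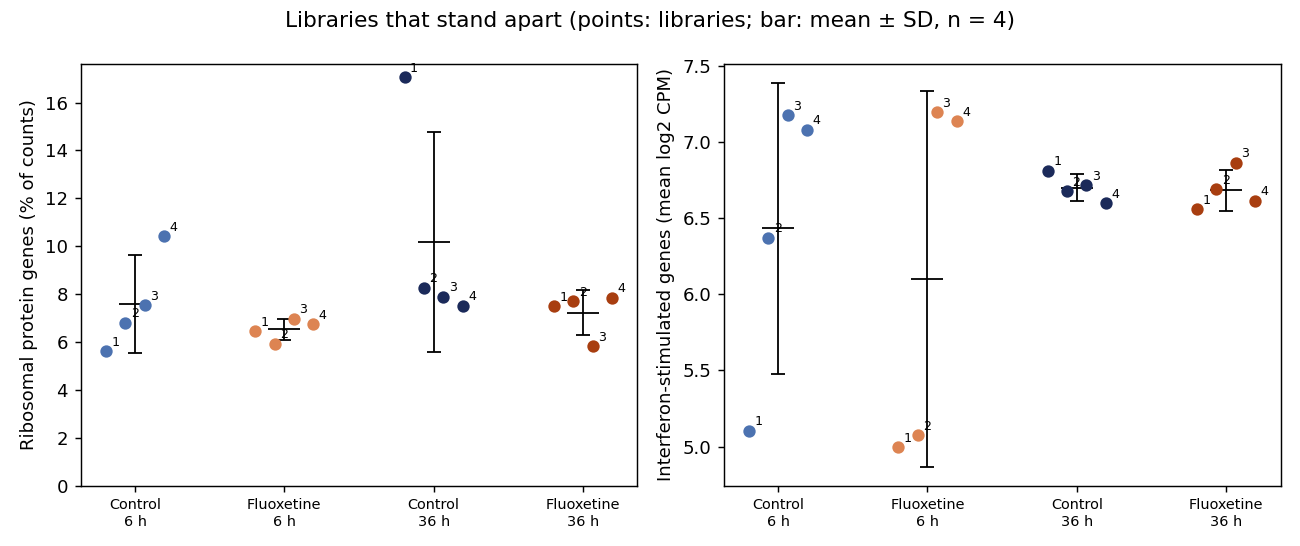
Share of counts from cytosolic ribosomal protein genes in percent (left) and mean log2 CPM of interferon-stimulated genes (right) for each library, with points numbered by replicate and bars showing mean ± SD of 4 libraries. Control replicate 1 at 36 h reached 17.1% ribosomal protein counts, and at 6 h the interferon-stimulated genes ranged from 4.99 to 7.20.

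Whether the exposure changed transcripts early was asked at 6 h. MKI67, the marker of cycling cells, stood at 194 ± 152 CPM in control and 190 ± 115 CPM in exposed cells (SD, n = 4), a log2 fold change of -0.030 ± 0.721 (SE). KRT14, a keratin of basal keratinocytes, stood at 967 ± 332 and 859 ± 170 CPM, and KRT6A, a keratin of wound-edge keratinocytes, at 2101 ± 1010 and 2096 ± 1220 CPM. The differentiation genes KRT10 (123 ± 45.5 and 113 ± 11.2 CPM) and IVL, which encodes involucrin (12.8 ± 3.92 and 12.5 ± 1.71 CPM), also differed by less than the spread between replicates. HMGCS1, an enzyme of cholesterol synthesis, had 121 ± 5.79 CPM in control and 144 ± 10.3 CPM in exposed cells, a log2 fold change of 0.25 ± 0.153 (SE).

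None of these 6 genes, and 0 of the 15627 tested, passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 6 h. At an unadjusted p under 0.05 there were 118 genes, where chance alone gives about 781. With a term for the 6 h replicates and 4 libraries left out, a setting chosen after seeing the data, there were 951 such genes of 16066, and 0 passed (smallest adjusted p 0.0777). The number thus depended on the libraries and terms used. A number under that given by chance is no evidence against an effect, since the p-values of the main fit may run too high. DESeq2 also called 0 genes, with 139 at an unadjusted p under 0.05, and limma-voom called 0, with 112. The authors' deposited table held 0 genes with an adjusted p under 0.05, and 165 of its 25301 genes with a p lay under 0.05 unadjusted. The median 95% confidence interval reached 0.542 to either side on the log2 scale, a 1.46-fold change, and for 73% of genes the whole interval lay within 2-fold. In simulated data of the same group sizes 29.9% of 67 genes changed 2-fold and 69.7% of 66 genes changed 4-fold were recovered. The simulation held the differences between replicates seen here only as gene-wise spread, not as changes that genes share. These shares may therefore be too high or too low for the real data. With sample quality weights, an alternative chosen after seeing the data, limma-voom called 2384 genes (1211 higher and 1173 lower). It gave control replicate 2 a weight of 11.3 and control replicate 4 a weight of 0.142.

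Of genes with a mean of at least 5 CPM over all libraries, those of smallest p that were higher in exposed cells at 6 h included FAM117B (ENSG00000138439, hg38 chromosome 2, 202635188 to 202769757), with 12.3 ± 0.793 CPM in control and 16 ± 0.398 CPM in exposed cells, a log2 fold change of 0.38 ± 0.129 (SE). XIAP, an inhibitor of caspases, had 21.0 ± 1.81 and 26.6 ± 2.64 CPM (log2 0.34 ± 0.122). TDG, a thymine DNA glycosylase of base excision repair, had 78.7 ± 3.89 and 92.0 ± 5.37 CPM (log2 0.23 ± 0.103). CNST, which encodes consortin, had 26.8 ± 2.15 and 32.2 ± 3.51 CPM, and the pseudogene SPCS2P4, whose reads are shared with its parent gene, had 3.56 ± 1.40 and 8.63 ± 4.41 CPM. The lower ones were the histone genes HIST1H3H (ENSG00000278828, chromosome 6, 27810064 to 27811300), with 2.86 ± 1.67 and 1.45 ± 0.0875 CPM, and HIST1H3E, with 1.37 ± 0.291 and 0.880 ± 0.275 CPM. With them were OSER1-DT (1.69 ± 0.664 and 0.665 ± 0.140 CPM) and GSTM4, a glutathione transferase (10.9 ± 1.29 and 8.56 ± 1.32 CPM). A gene whose symbol the table gives as a date (ENSG00000099785, chromosome 19, 8413270 to 8439017) had 12.7 ± 2.52 and 9.64 ± 1.75 CPM. All 10 had an edgeR adjusted p = 1.

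Of the 34 gene lists tested with camera at a preset correlation, 4 lay lower in exposed cells at 6 h, with 0 members past the threshold over all genes and 0 adjusted over the list alone in each. Cytosolic ribosomal protein genes (77 tested) had a median log2 fold change of -0.26 (adjusted p = 1.62e-08), with RPL10 at 1754 ± 551 and 1454 ± 310 CPM in control and exposed cells. The exposure effect at 6 h correlated with gene length across 10853 genes, which are not independent replicates (Spearman's rho 0.487). The deviation of control replicate 4 from its group did so at -0.521. Nuclear-encoded oxidative phosphorylation genes (71 tested) had a median of -0.16 (adjusted p = 7.27e-05), with ATP5MC2, a subunit of ATP synthase, at 234 ± 56.2 and 193 ± 18.3 CPM and NDUFB8, a subunit of complex I, at 10.5 ± 2.14 and 8.26 ± 1.08 CPM. Interferon-stimulated genes (39 tested) had a median of -0.15 (adjusted p = 0.000606), with IFITM3 at 1183 ± 453 and 969 ± 357 CPM and IFI44 at 66.7 ± 42.5 and 52.6 ± 31.6 CPM. Replication-dependent histone genes (16 tested) had a median of -0.21 (adjusted p = 0.0284), with HIST1H2BO at 0.451 ± 0.213 and 0.233 ± 0.125 CPM. For each of these 4 lists the call was lost, at an adjusted p = 0.855 with an estimated correlation. The rotation test fry, which asks whether a list's genes move on balance in the same direction, gave 0 lists, with a smallest adjusted p of 0.997. Without control replicate 4, the library with the high ribosomal protein share, 0 lists passed. There were 9 without control replicate 1, 7 without control replicate 2, 8 without fluoxetine replicate 3 and 8 without fluoxetine replicate 4. The interferon call was also lost without control replicate 3 and without fluoxetine replicates 1 or 2, at an adjusted p of up to 0.8. The oxidative phosphorylation call was also lost without fluoxetine replicate 4, and the histone call without control replicate 3 or fluoxetine replicates 1, 2 or 3. When the 3 libraries that stand apart were left out, 0 lists passed and the median of the ribosomal protein genes was -0.019.

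The lists closest to the stated purpose gave no call at 6 h with all libraries. Some did at the preset correlation with 1 library left out. YAP/TAZ target genes (adjusted p = 0.0743 with all) were called higher without control replicate 1 or 2 or fluoxetine replicate 3 or 4 (0.00331 to 0.0403). EGFR ligands and receptors were called higher without control replicate 1 or 2 (0.00987 and 0.0409). G2/M genes were called higher without control replicate 1 or fluoxetine replicate 3 or 4 (0.00388 to 0.00999). They were called lower without control replicate 3 or fluoxetine replicate 1 or 2 (0.0233 to 0.0357). Growth factor response genes stood at an adjusted p = 0.0736 and were called in none of these fits. Median log2 fold changes were 0.0094 for G1/S and 0.054 for G2/M cell cycle genes, 0.11 for growth factor response genes, 0.087 for EGFR ligands and receptors, 0.11 for YAP/TAZ target genes, 0.011 for wound-edge genes (mean -0.054) and 0.050 for actin and migration genes. Lists tied to known actions of cationic amphiphilic drugs had medians of -0.056 for lysosome, -0.029 for autophagy and 0.047 for cholesterol genes. SQSTM1, the autophagy receptor p62, had 417 ± 117 CPM in control and 370 ± 121 CPM in exposed cells. The transporter gene SLC6A4 had 17 counts in all 16 libraries together, with at most 5 in a library, and was too low to test. A count of 0 allows up to 3 counts, or 0.0972 to 0.189 CPM in these libraries, and such floors and intervals cover counting error only. Of the serotonin genes that were tested, HTR7, a serotonin receptor, had 8.06 CPM in control and 8.18 CPM in exposed cells, and MAOA, which degrades serotonin, had 34.3 and 35.2 CPM.

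At 36 h the same questions were asked of the longer exposure. MKI67 stood at 59.8 ± 36.3 CPM in control and 65.7 ± 30.7 CPM in exposed cells (SD, n = 4), a log2 fold change of 0.13 ± 0.724 (SE). KRT14 had 450 ± 46.2 and 362 ± 125 CPM, KRT10 had 42.3 ± 6.69 and 38.3 ± 14.8 CPM, and KRT6A had 220 ± 73.4 and 240 ± 47.8 CPM. IVL had 18.5 ± 8.74 and 15 ± 0.155 CPM, HMGCS1 had 64.9 ± 3.86 and 71.7 ± 21.2 CPM, and SQSTM1 had 808 ± 185 and 883 ± 300 CPM. None passed, with edgeR adjusted p-values of 0.75 or more.

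Again 0 genes passed edgeR's test at 36 h, with 925 at an unadjusted p under 0.05 and 781 given by chance. Leaving out 1 of the 8 libraries at 36 h moved this number to between 193 (without control replicate 1 at 36 h) and 1987 (without control replicate 4 at 36 h), so whether it exceeds chance depends on single libraries. DESeq2 called 0 with 1111 at an unadjusted p under 0.05, and limma-voom called 0 with 239. The authors' deposited table held 0 genes with an adjusted p under 0.05 and 350 of 26680 under 0.05 unadjusted. The median 95% interval reached 0.538 to either side on the log2 scale (1.45-fold), and for 65.5% of genes it lay within 2-fold. Leaving out the 3 libraries that stand apart, edgeR called 0 genes, with 172 at an unadjusted p under 0.05 and a smallest adjusted p of 0.122, and the intervals of 84.3% of genes lay within 2-fold. With sample quality weights limma-voom called 2 genes, 1 higher and 1 lower. When the 3 libraries and control replicate 2 at 6 h were left out and a term for the 6 h replicates was added, edgeR called 1 gene, GPR89B, at a log2 fold change of -1.51 (edgeR adjusted p = 0.00316). GPR89B was named after its value was seen, and it shares reads with the near-identical GPR89A, so its level is uncertain.

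The genes of smallest p, among those with a mean of at least 5 CPM over all libraries, that were higher in exposed cells at 36 h were ZFP69 (4.05 ± 0.307 and 5.29 ± 0.354 CPM, log2 0.39 ± 0.139 SE) and ADAM23 (16.1 ± 2.25 and 20.9 ± 4.35 CPM). They also included ARSB, the lysosomal arylsulfatase B (9.37 ± 1.82 and 12.7 ± 1.67 CPM), SS18L1 (22.0 ± 3.82 and 27.8 ± 2.84 CPM) and IKBKG, the NEMO subunit of the IKK complex, which has a near-identical pseudogene (12.9 ± 1.08 and 17.7 ± 3.25 CPM). The lower ones were AL078621.1 (ENSG00000144158, chromosome 2, 113657908 to 113658675; 6.85 ± 2.76 and 3.80 ± 0.194 CPM, log2 -0.84 ± 0.219 SE), and LSM6, a component of RNA-binding LSM rings (9.56 ± 5.47 and 4.49 ± 0.452 CPM). CKMT1B, a mitochondrial creatine kinase with a near-identical copy, had 59.1 ± 17.9 and 31.8 ± 12.4 CPM, TMA7 had 6.90 ± 4.10 and 3.37 ± 0.665 CPM, and HEATR3 had 15.2 ± 1.97 and 12 ± 0.334 CPM. All 10 had an edgeR adjusted p = 0.714.

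Camera with a preset correlation called 3 lists at 36 h, again with 0 members past the threshold over all genes and 0 adjusted over the list alone. Cytosolic ribosomal protein genes had a median log2 fold change of -0.73 (adjusted p = 1.64e-22), with RPS9 at 2295 ± 2050 CPM in control and 1104 ± 140 CPM in exposed cells and RPL24 at 882 ± 804 and 422 ± 55.2 CPM. Oxidative phosphorylation genes had a median of -0.65 (adjusted p = 7.6e-19), with NDUFA11 of complex I at 18.4 ± 19.0 and 7.28 ± 1.29 CPM and UQCR11 of complex III at 21.4 ± 10.9 and 13.3 ± 2.69 CPM. PI3K, AKT and MTOR pathway genes (27 tested) had a median of 0.26 (adjusted p = 0.0106), with IRS2, an insulin receptor substrate, at 20.6 ± 5.29 and 30.3 ± 10.4 CPM, while EIF4EBP1, a repressor of translation, went the other way at 69.5 ± 46.7 and 44.7 ± 4.44 CPM. For each of the 3 lists the call was lost, at an adjusted p = 0.987 with an estimated correlation, and fry gave 0 lists with a smallest adjusted p of 0.901. Control replicate 1 had 17.1% ribosomal protein counts, and its deviation from its group correlated with gene length at a Spearman's rho of -0.496. For the exposure effect at 36 h this was 0.553. Without control replicate 1 the adjusted p was 6.1e-07 for the ribosomal protein list, 4.47e-08 for the oxidative phosphorylation list and 0.122 for the PI3K, AKT and MTOR list, and 14 lists passed. There were 7, 5, 10 and 8 lists without fluoxetine replicates 1, 2, 3 and 4 in turn. Without the 3 libraries that stand apart 0 lists passed, with medians of -0.039 and -0.034 for the ribosomal protein and oxidative phosphorylation lists. Median log2 fold changes at 36 h were -0.031 for G1/S, 0.0093 for G2/M (mean -0.046), 0.20 for growth factor response, 0.18 for YAP/TAZ target, 0.090 for wound-edge (mean -0.0035) and -0.081 for lysosome genes, none past the threshold with all libraries. With 1 library left out some were called at the preset correlation. YAP/TAZ target genes were higher without control replicates 2 or 3 or fluoxetine replicate 3. Growth factor response genes were higher without control replicate 1 or fluoxetine replicates 1 or 4. Lysosome genes were higher without control replicate 1. Other lists called this way included cholesterol genes, higher without control replicate 1 (adjusted p = 1.64e-05) and lower without fluoxetine replicate 3 (0.00141). NRF2 target genes turned in the same way (6.83e-05 and 0.000947). G1/S and G2/M genes were both lower without control replicate 1 and both higher without fluoxetine replicate 3. G1/S genes were also lower without fluoxetine replicate 4.

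Whether the exposure acted differently at the late and the early time was tested as the difference between the 2 effects. CKMT1B went from 37.8 ± 5.51 to 50.1 ± 12.2 CPM with exposure at 6 h and from 59.1 ± 17.9 to 31.8 ± 12.4 CPM at 36 h, a difference of -1.30 ± 0.393 (SE) on the log2 scale. SPCS2P4 had a difference of -2.69 ± 0.819 (SE), AL078621.1 of -0.78 ± 0.304 (SE) and HEATR3 of -0.40 ± 0.160 (SE). WDR19, a gene of intraflagellar transport, had 10.7 ± 1.23 and 9.31 ± 0.784 CPM at 6 h and 24.1 ± 1.5 and 30.2 ± 5.54 CPM at 36 h, a difference of 0.52 ± 0.195 (SE). Among genes with a mean of at least 5 CPM these 5 had the smallest p, and for each the edgeR adjusted p = 1. Of all genes 0 passed edgeR's test, 91 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 with 96 and 90 at an unadjusted p under 0.05. With a term for the 6 h replicates and 4 libraries left out 668 genes had an unadjusted p under 0.05 and 0 passed (smallest adjusted p 0.64). With sample quality weights limma-voom called 355 genes (138 higher and 217 lower).

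Camera called 5 lists for this difference with the preset correlation, with 0 members past the threshold over all genes and 0 adjusted over the list alone. Medians were -0.51 for oxidative phosphorylation, -0.47 for ribosomal protein, -0.077 for ribosome biogenesis, 0.24 for mitochondrially encoded and 0.11 for interferon-stimulated genes. The difference correlated with gene length across genes (Spearman's rho 0.438). All 5 calls were lost, at an adjusted p = 0.952 with an estimated correlation, and 0 lists passed without the 3 libraries that stand apart. Leaving out control replicate 1 at 36 h raised the adjusted p of the oxidative phosphorylation list to 0.675 and of the ribosomal protein list to 0.0732. Without that library 10 lists passed, without control replicates 2, 3 or 4 at 36 h 3 lists, and without fluoxetine replicates 3 or 4 at 36 h 8 lists. The call of the mitochondrially encoded genes was lost without control replicate 4 or fluoxetine replicates 1 or 2 at 6 h and without control replicate 1 or fluoxetine replicate 2 at 36 h (adjusted p of up to 0.117). The ribosome biogenesis call was lost without control replicates 1 or 2 or fluoxetine replicates 3 or 4 at 6 h and without control replicates 2, 3 or 4 or fluoxetine replicate 3 at 36 h (up to 0.814). The interferon call was lost without control replicates 3 or 4 or fluoxetine replicates 1 or 2 at 6 h and without control replicates 2, 3 or 4 or fluoxetine replicates 2 or 3 at 36 h (up to 0.908). Across genes, which are not independent replicates, the exposure effects at 36 h and 6 h correlated at r = 0.302 (Spearman's rho 0.486). The correlation fell to 0.0092 without control replicate 4 at 6 h, to 0.0387 without control replicate 1 at 36 h and to -0.0099 without the 3 libraries.

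Time in culture without exposure was compared as control cells at 36 h against 6 h. CDC6, which loads the replicative helicase, fell from 110 ± 5.32 to 8.60 ± 1.63 CPM (SD, n = 4), a log2 fold change of -3.67 ± 0.192 (SE; edgeR adjusted p = 5.2e-09). FOSL1, an AP-1 transcription factor (ENSG00000175592, chromosome 11, 65892049 to 65900573), fell from 297 ± 67.8 to 18.9 ± 1.86 CPM (log2 -3.97 ± 0.182; edgeR adjusted p = 1.63e-09). BHLHE41, a repressor in the circadian clock (ENSG00000123095, chromosome 12, 26120026 to 26125127), rose from 10.9 ± 0.694 to 117 ± 6.85 CPM (log2 3.42 ± 0.155; edgeR adjusted p = 1.62e-09). TXNIP, an inhibitor of thioredoxin and glucose uptake, rose from 9.98 ± 2.37 to 296 ± 116 CPM (log2 4.89 ± 0.394; edgeR adjusted p = 1.85e-07).

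In edgeR's test 7696 genes changed in control cells, 4037 higher and 3659 lower at 36 h, of which 2684 and 1672 changed at least 2-fold. With upper-quartile scaling, which moved the median of all genes by 0.194 on the log2 scale, 5231 were higher and 2752 lower, so 65.5% of the calls were higher against 52.5%. Without the 3 libraries that stand apart 10263 genes changed, 7407 of them among the 7696. The authors' deposited table held 3569 higher and 3247 lower genes at an adjusted p under 0.05.

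Among the largest increases were genes near the detection limit at 6 h, whose fitted fold changes depend on the prior count and are no bound. C2CD4A, TCIM, SNCAIP, YPEL2, SH2D3C and TG had means of 0.120 to 0.547 CPM at 6 h and 9.91 to 18.8 CPM at 36 h, with log2 fold changes of 4.86 to 6.48. The olfactory receptor family gene OR2I1P rose from 1.24 ± 0.823 to 53 ± 27.9 CPM. BMF, a BH3-only inducer of apoptosis, rose from 2.95 ± 0.758 to 102 ± 6.50 CPM (edgeR adjusted p = 1.16e-08). AMTN, an enamel protein gene, passed at an edgeR adjusted p = 0.0362 with 218 CPM in control replicate 1 at 36 h, against 2.64 to 2.80 CPM in the other libraries of the group. Without that library its log2 fold change was 0.47 (edgeR adjusted p = 0.789), and the call was also lost without any 1 of the control libraries at 6 h (up to 0.0855). SPRR2A, a cornified envelope precursor with near-identical family members, fell from 17.8 ± 6.47 to 0.121 ± 0.130 CPM, near the floor of 3 counts (0.138 to 0.189 CPM). KRT6B, another wound-edge keratin, fell from 10.1 ± 7.02 to 0.174 ± 0.0992 CPM. FST, the activin antagonist follistatin, fell from 406 ± 18.2 to 14.3 ± 8.48 CPM, SERPINB2 from 585 ± 104 to 21.0 ± 10.2 CPM and PTHLH from 448 ± 158 to 21.8 ± 5.37 CPM. THBS1, the matrix protein thrombospondin 1, fell from 1560 ± 873 to 93.9 ± 41.3 CPM, and CALB2 from 11.7 ± 7.20 to 0.830 ± 0.805 CPM. MCM10 and RRM2, of DNA replication and nucleotide supply, fell from 93.7 ± 12.2 to 4.29 ± 2.48 CPM and from 114 ± 12.9 to 5.63 ± 2.80 CPM. KRT6A fell by 3.25 ± 0.471 (SE), KRT10 fell by 1.54 ± 0.3, KRT14 fell by 1.10 ± 0.279 and HMGCS1 fell by 0.90 ± 0.155 on the log2 scale, while SQSTM1 rose by 0.95 ± 0.282. MKI67 (log2 -1.70 ± 0.741 SE; edgeR adjusted p = 0.07) and IVL (log2 0.52 ± 0.260 SE; edgeR adjusted p = 0.108) did not pass. Without control replicate 4 at 6 h both passed, at edgeR adjusted p-values of 0.0408 and 0.0314, as they did without the 3 libraries that stand apart (0.0345 and 0.0305).

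Camera called 15 lists in control cells, 7 higher and 8 lower, with the preset correlation, and fry called 18 (smallest adjusted p 3.12e-09). Of 50 G1/S genes 49 fell, 50 adjusted over the list alone, with a median of -2.08 (adjusted p = 0.106 with an estimated correlation); MCM7 of the replicative helicase fell from 1219 ± 107 to 308 ± 25.4 CPM and FEN1, a flap endonuclease, from 248 ± 34.6 to 32.6 ± 5.53 CPM. Of 50 G2/M genes 38 fell, 42 adjusted over the list alone, with a median of -1.66 (adjusted p = 0.648 with an estimated correlation). Among them were CDK1, from 106 ± 22.6 to 21.6 ± 7.36 CPM, CCNB1, which encodes cyclin B1, and the mitotic kinase AURKB. G2/M genes also differed between the 6 h libraries, where replicates 3 and 4 lay below replicates 1 and 2 by a median log2 difference of -1.05 in control cells. Of 35 ribosome biogenesis genes 32 fell by either adjustment, with a median of -1.87 (adjusted p = 0.0833 with an estimated correlation); LYAR fell from 76.2 ± 5.66 to 12.4 ± 2.12 CPM, RRS1 from 184 ± 15.2 to 36.2 ± 3.38 CPM and RRP12 from 227 ± 7.89 to 64.8 ± 9.59 CPM. Of 19 heat shock genes 17 fell by either adjustment, with a median of -1.35 (adjusted p = 0.318 with an estimated correlation). HSPA8, the constitutive HSP70, fell from 4944 ± 796 to 691 ± 116 CPM, HSPD1 from 1218 ± 265 to 275 ± 26.1 CPM and STIP1 from 541 ± 62.8 to 159 ± 16 CPM.

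Of 33 unfolded protein response and ATF4 target genes 19 fell and 5 rose by either adjustment, with a median of -0.62 (adjusted p = 0.106 with an estimated correlation). HSPA5, the chaperone BiP, fell from 1758 ± 276 to 552 ± 20.1 CPM and MTHFD2, a mitochondrial folate enzyme, from 113 ± 11 to 28.3 ± 5.74 CPM, whereas DDIT4, an inhibitor of mTORC1, rose from 103 ± 15.6 to 667 ± 46.9 CPM. Of 42 actin and migration genes 22 fell and 1 rose by either adjustment, with a median of -0.49 (adjusted p = 0.0833 with an estimated correlation). ACTB fell from 9965 ± 353 to 2553 ± 992 CPM, TPM4, a tropomyosin, from 1054 ± 168 to 269 ± 30.5 CPM and the calpain CAPN2 from 665 ± 44.0 to 260 ± 22.2 CPM. Of 28 cell junction genes 10 fell and 3 rose by either adjustment, with a median of -0.31 (adjusted p = 0.648 with an estimated correlation), a call also lost without the 3 libraries that stand apart (adjusted p = 0.239); the connexin gene GJB2 fell from 29.4 ± 12.1 to 4.88 ± 1.76 CPM and PKP3, a plakophilin, from 803 ± 96.2 to 398 ± 23.9 CPM. Of 71 oxidative phosphorylation genes 13 fell, 9 adjusted over the list alone, with a median of -0.13 that was 0.0545 with upper-quartile scaling (adjusted p = 0.891 with an estimated correlation). In the fit that leaves out the 3 libraries that stand apart 56 of the 71 fell, with a median of -0.554 (adjusted p = 0.533 with an estimated correlation). CYCS, which encodes cytochrome c, fell from 421 ± 125 to 140 ± 48.4 CPM and ATP5F1B from 1603 ± 54.4 to 931 ± 98.3 CPM.

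Among the lists that lay higher, 13 of 16 replication-dependent histone genes rose and 1 fell, 14 and 1 adjusted over the list alone, with a median of 2.55 (adjusted p = 0.0993 with an estimated correlation). Most such transcripts lack a poly(A) tail, and poly(A)-enriched libraries hold those that have one. HIST1H2AG rose from 3.24 ± 1.07 to 25.2 ± 2.90 CPM, HIST1H2AC from 19.5 ± 8.63 to 120 ± 13.6 CPM and HIST1H2BD from 12.2 ± 4.76 to 76.6 ± 33.2 CPM. Of 17 circadian clock genes 10 rose and 2 fell, 11 and 2 adjusted over the list alone, with a median of 0.85 (adjusted p = 0.143 with an estimated correlation); DBP rose from 14.8 ± 4.21 to 93.7 ± 48.9 CPM and PER1 from 5.59 ± 1.25 to 19.9 ± 3.04 CPM. Of 39 lysosome genes 22 rose and 0 fell by either adjustment, with a median of 0.49 (adjusted p = 0.318 with an estimated correlation); the cathepsin genes CTSS and CTSK rose from 19.6 ± 7.88 to 92.9 ± 12.5 CPM and from 0.744 ± 0.191 to 4.15 ± 0.361 CPM. Of 42 autophagy genes 20 rose and 4 fell, 21 and 5 adjusted over the list alone, with a median of 0.43 (adjusted p = 0.13 with an estimated correlation). ULK1, the kinase that starts autophagy, rose from 21.0 ± 5.42 to 141 ± 29.3 CPM, and the autophagy receptors OPTN and BNIP3L rose from 107 ± 12.4 to 361 ± 73.8 CPM and from 28.0 ± 5.26 to 84.4 ± 10.2 CPM.

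Of 25 p53 target genes 12 rose and 1 fell, 13 and 2 adjusted over the list alone, with a median of 0.63 (adjusted p = 0.106 with an estimated correlation). BBC3, which encodes PUMA, rose from 4.90 ± 1.04 to 57.3 ± 38.5 CPM, TP53INP1 from 6.93 ± 3.86 to 82.1 ± 16.5 CPM and the antiproliferative BTG2 from 45.5 ± 13.7 to 222 ± 22.6 CPM, while AEN, an apoptotic nuclease, fell from 122 ± 21.5 to 14.1 ± 3.12 CPM. Of 30 inflammatory cytokine and NF-kB target genes 15 rose and 2 fell by either adjustment, with a median of 0.85 (adjusted p = 0.106 with an estimated correlation); the chemokine CCL2 rose from 5.77 ± 2.27 to 114 ± 65.9 CPM, SOD2 from 105 ± 25.8 to 448 ± 172 CPM and NFKBIA from 91.9 ± 14 to 209 ± 10.7 CPM. Of 19 antigen presentation genes 6 rose, 5 adjusted over the list alone, with a median of 0.71 (adjusted p = 0.788 with an estimated correlation); TAPBP rose from 276 ± 5.89 to 636 ± 57.5 CPM, HLA-E from 339 ± 75.8 to 592 ± 73.0 CPM and CIITA, the class II transactivator, from 2.11 ± 0.479 to 22.0 ± 13.3 CPM. Markers of other cell types differed as well, with summed fibroblast markers at 9.80 ± 1.46 CPM at 6 h and 38.8 ± 4.14 CPM at 36 h and endothelial markers at 9.56 ± 1.70 and 26.9 ± 9.73 CPM. Only 4 fibroblast and 2 endothelial markers had enough counts to be tested, so these sums do not show that other cells were present. The p53 call was lost without control replicate 1 at 36 h (adjusted p = 0.0668), the antigen presentation call without that library or control replicates 1 or 2 at 6 h (up to 0.129), the cell junction call without that library or control replicate 1 at 6 h (up to 0.307), and the oxidative phosphorylation call without control replicate 4 at 6 h or replicates 2, 3 or 4 at 36 h (up to 0.162).

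The remaining lists gave no call in control cells with time when all libraries were used. Of all 15627 tested genes 4037 were higher and 3659 lower, so changed members alone are no sign that a list moved. Few of the ribosomal protein, interferon-stimulated and mitochondrially encoded genes changed. The YAP/TAZ list (adjusted p = 0.0546) was called lower when any 1 of 5 libraries was left out (0.00935 to 0.0393). Ribosomal protein genes were called higher without control replicate 4 at 6 h (0.0264). NRF2 target genes were called lower without control replicate 1 at 36 h (0.0253). Of 33 wound-edge genes 11 fell and 3 rose, of 23 YAP/TAZ target genes 8 fell and 2 rose, of 20 basal keratinocyte genes 8 fell and 3 rose, and of 18 suprabasal genes 4 fell and 2 rose. Of 14 cornified envelope genes 4 rose and 3 fell, of 16 Notch pathway genes 4 rose and 2 fell, and of 30 extracellular matrix genes 7 rose and 6 fell. Of 36 growth factor response genes 13 rose and 5 fell, of 12 EGFR ligands and receptors 4 rose and 4 fell, and of 27 PI3K, AKT and MTOR genes 9 rose and 8 fell. Of 25 cholesterol genes 8 rose and 2 fell, of 26 fatty acid genes 10 rose and 3 fell, of 20 xenobiotic metabolism genes 10 rose and 3 fell, and of 27 NRF2 target genes 3 rose and 5 fell. Of 33 hypoxia and glycolysis genes 9 rose and 13 fell, of 39 interferon-stimulated genes 3 rose and 1 fell, of 77 ribosomal protein genes 1 rose and 2 fell, of 15 mitochondrially encoded genes 1 fell, and of 10 serotonin genes 2 rose and 3 fell. Adjusted over the list alone, the counts of these 19 lists were 13 and 5 (growth factor), 5 and 4 (EGFR), 3 and 8 (basal), 2 and 4 (suprabasal), 5 and 3 (cornified), 2 and 10 (wound-edge), 7 and 6 (matrix), 2 and 8 (YAP/TAZ) and 4 and 2 (Notch) higher and lower. They were 2 and 3 (serotonin), 7 and 1 (cholesterol), 10 and 3 (fatty acid), 3 and 5 (NRF2), 9 and 14 (hypoxia), 0 and 0 (mitochondrial), 0 and 0 (ribosomal protein), 2 and 0 (interferon), 11 and 3 (xenobiotic) and 11 and 8 (PI3K). Medians and means differed in sign for 6 of these lists, at 0.25 and -0.24 for EGFR, -0.24 and 0.097 for suprabasal, 0.41 and -0.69 for cornified, -0.037 and 0.28 for Notch, -0.11 and 0.057 for NRF2 and 0.0058 and -0.022 for hypoxia genes. The counts higher and lower without the 3 libraries that stand apart were 9 and 9 for cholesterol (median 0.147 against 0.592), 11 and 6 for fatty acid (0.0909 against 0.37), 15 and 9 for growth factor response (0.0928 against 0.333) and 2 and 18 for NRF2 target genes. The NRF2 list passed camera's preset test without these libraries, with a median of -0.75 (adjusted p = 0.00474), and not with the estimated one (adjusted p = 0.533 with an estimated correlation).

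**Figure D3:**
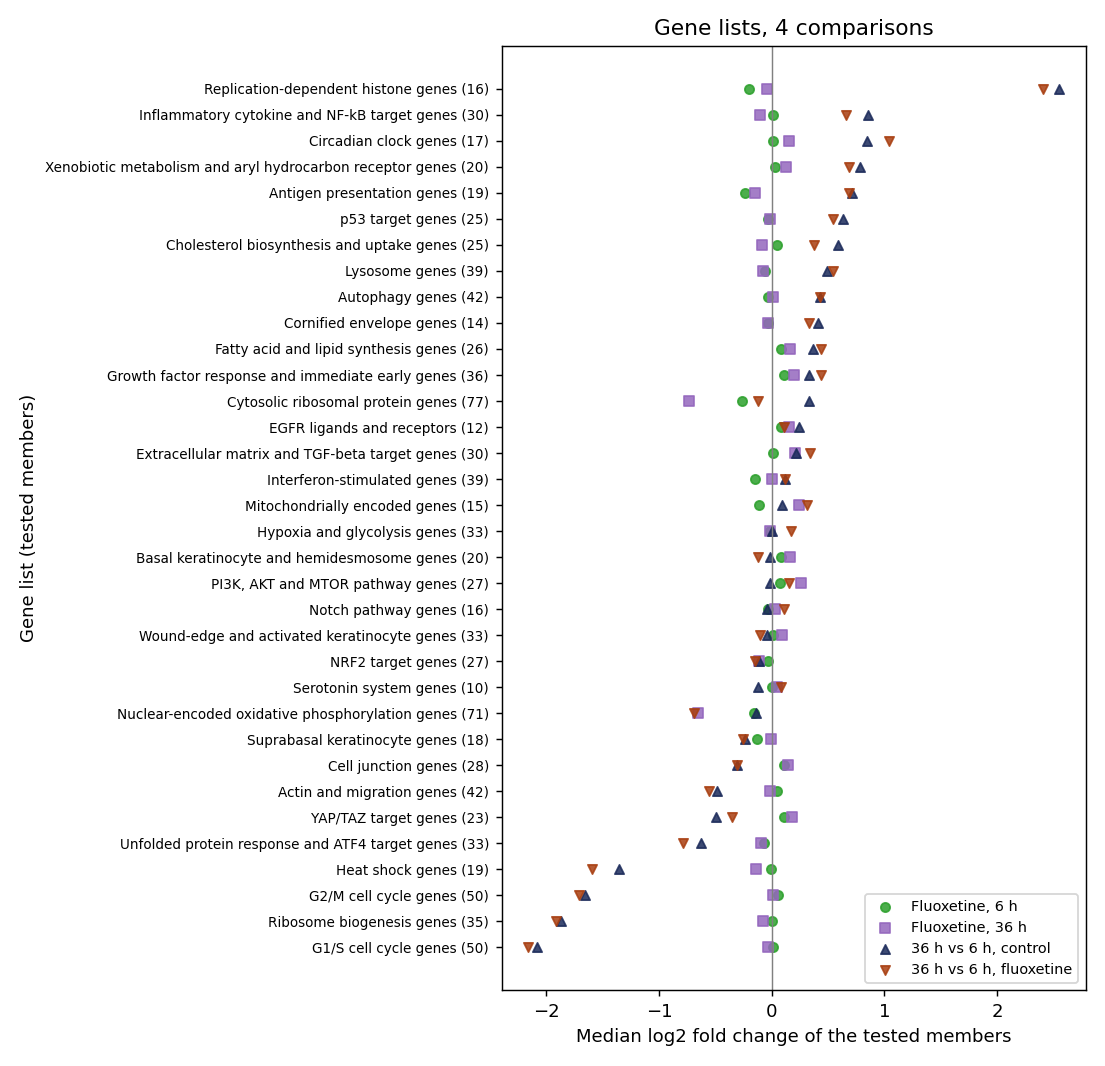
Median log2 fold change of the tested members of each of 34 gene lists (number tested in brackets) in 4 comparisons, with circles and squares for fluoxetine against control at 6 h and 36 h and triangles for 36 h against 6 h in control and in exposed cells. G1/S genes reach -2.08 and -2.16 with time, and the exposure medians furthest from 0 are those of ribosomal protein (-0.73) and oxidative phosphorylation genes (-0.65) at 36 h, which were -0.039 and -0.034 without the 3 libraries that stand apart.

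Exposed cells were compared between 36 h and 6 h in the same way. CDC6 fell from 112 ± 3.40 to 8.21 ± 2.19 CPM (SD, n = 4), FOSL1 from 349 ± 14.4 to 22.5 ± 3.39 CPM and HSPA8 from 5043 ± 1250 to 628 ± 26.7 CPM. BHLHE41 rose from 10.6 ± 0.406 to 140 ± 35.7 CPM, TXNIP from 8.12 ± 1.59 to 304 ± 111 CPM and DDIT4 from 83.7 ± 8.06 to 687 ± 67.4 CPM. ISLR2 and CP, which encodes the copper carrier ceruloplasmin, were among the 10 largest increases in exposed cells, from 0.627 ± 0.066 to 18.8 ± 8.90 CPM and from 0.863 ± 0.903 to 27.8 ± 15.8 CPM. The other 8 were TCIM, C2CD4A, TG, OR2I1P, SNCAIP, SH2D3C, BMF and TXNIP, with fitted log2 fold changes of 5.23 to 6.79. The 10 largest decreases were SPRR2A, FST, SERPINB2, KRT6B, RRM2, MCM10, PTHLH, THBS1, FOSL1 and CALB2, the same 10 genes as in control cells. SPRR2A had 17.2 ± 1.43 CPM at 6 h and 0 counts in 3 of the 4 libraries at 36 h, and the other 9 had fitted log2 fold changes of -5.45 to -3.88. KRT6A fell by 3.13 ± 0.468 (SE), KRT10 fell by 1.56 ± 0.3, KRT14 fell by 1.25 ± 0.280 and HMGCS1 fell by 1.01 ± 0.155 on the log2 scale, while SQSTM1 rose by 1.25 ± 0.284. MKI67 (log2 -1.53 ± 0.738 SE; edgeR adjusted p = 0.0937) and IVL (log2 0.26 ± 0.259 SE; edgeR adjusted p = 0.42) did not pass.

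edgeR's test called 8106 genes in exposed cells, 4137 higher and 3969 lower, of which 2718 and 1922 changed at least 2-fold. With upper-quartile scaling, which moved the median of all genes by 0.209, there were 5386 higher and 2974 lower, and 64.4% of the calls were higher against 51%. Leaving out the 3 libraries that stand apart, 10732 genes changed, 7981 of them among the 8106. The authors' deposited table held 5551 higher and 5145 lower genes at an adjusted p under 0.05. Across genes the time effects in exposed and control cells correlated at r = 0.942 (Spearman's rho 0.941). There were 3477 genes higher with time in both, where independent lists would share 1069, 3380 lower in both against 929.3, and 0 with opposite calls. The 2 comparisons share no libraries, and 0 genes differed between them in the test of the difference given above.

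Camera called 12 lists in exposed cells with the preset correlation, 5 higher and 7 lower, and fry called 19 (smallest adjusted p 1.56e-09). Summed fibroblast markers stood at 9.88 ± 1.39 CPM at 6 h and 52.0 ± 22.5 CPM at 36 h in these cells, and endothelial markers at 10.8 ± 2.79 and 32.5 ± 1.68 CPM. Of 50 G1/S genes 49 fell, 50 adjusted over the list alone, with a median of -2.16 (adjusted p = 0.123 with an estimated correlation), among them MCM7, from 1214 ± 132 to 272 ± 40.6 CPM. Of 50 G2/M genes 42 fell, 43 adjusted over the list alone, with a median of -1.71 (adjusted p = 0.685 with an estimated correlation); CDK1 fell from 104 ± 31.0 to 19.3 ± 7.39 CPM. At 6 h exposed replicates 3 and 4 lay below replicates 1 and 2 in this list by a median log2 difference of -1.23. Of 35 ribosome biogenesis genes 34 fell by either adjustment, with a median of -1.91 (adjusted p = 0.078 with an estimated correlation), with LYAR from 76.5 ± 3.76 to 10.2 ± 1.56 CPM and RRS1 from 181 ± 17.2 to 36.3 ± 2.92 CPM. Of 19 heat shock genes 17 fell by either adjustment, with a median of -1.59 (adjusted p = 0.312 with an estimated correlation). Of 33 unfolded protein response genes 19 fell and 5 rose by either adjustment (adjusted p = 0.123 with an estimated correlation), with HSPA5 falling from 1680 ± 166 to 519 ± 114 CPM and the stress factor ATF3 rising from 4.77 ± 0.502 to 28.9 ± 14.7 CPM. Of 42 actin and migration genes 20 fell and 2 rose by either adjustment (adjusted p = 0.078 with an estimated correlation), with ACTB from 10180 ± 504 to 2323 ± 518 CPM. Of 71 oxidative phosphorylation genes 29 fell and 1 rose by either adjustment, with a median of -0.69 (adjusted p = 0.849 with an estimated correlation), with CYCS from 412 ± 66.0 to 108 ± 10.9 CPM. With the 3 libraries that stand apart left out, 62 fell and 1 rose (median -0.591), close to the 56 in control cells (adjusted p = 0.564 with an estimated correlation).

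Higher in exposed cells at 36 h were 13 of 16 histone genes, with 1 lower, by either adjustment (median 2.41; adjusted p = 0.107 with an estimated correlation), among them HIST1H3H from 1.45 ± 0.0875 to 13.5 ± 1.21 CPM and HIST1H2AG from 2.92 ± 0.684 to 26.5 ± 1.58 CPM. Of 17 circadian genes 11 rose and 2 fell, 12 and 2 adjusted over the list alone (median 1.04; adjusted p = 0.123 with an estimated correlation). Of 39 lysosome genes 20 rose and 2 fell by either adjustment (median 0.54; adjusted p = 0.352 with an estimated correlation), with CTSS from 16.7 ± 1.56 to 84.4 ± 12 CPM. Of 42 autophagy genes 17 rose and 6 fell by either adjustment (median 0.43; adjusted p = 0.131 with an estimated correlation), with ULK1 from 19.5 ± 5.71 to 171 ± 84.9 CPM. Of 25 p53 target genes 15 rose and 2 fell by either adjustment (median 0.54; adjusted p = 0.123 with an estimated correlation), with BBC3 from 4.22 ± 1.25 to 46.3 ± 13.7 CPM. The inflammatory, antigen presentation and cell junction lists, called in control cells, had camera adjusted p-values of 0.0549, 0.0713 and 0.0937 in exposed cells. In the test of the difference between the exposure effects their adjusted p-values were 0.373, 0.747 and 0.747. In exposed cells camera called the inflammatory list higher without fluoxetine replicate 2 at 6 h (0.0438) or replicate 3 at 36 h (0.0244). It called the antigen presentation list higher without fluoxetine replicates 3 or 4 at 6 h (0.0359 and 0.0413) or replicate 3 at 36 h (0.00943). Without the 3 libraries that stand apart the preset correlation gave 15 lists in each of the 2 time comparisons. With an estimated correlation the G1/S list then passed, at an adjusted p of 0.00159 in control and 0.00193 in exposed cells, and no other list did.

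**Figure D4:**
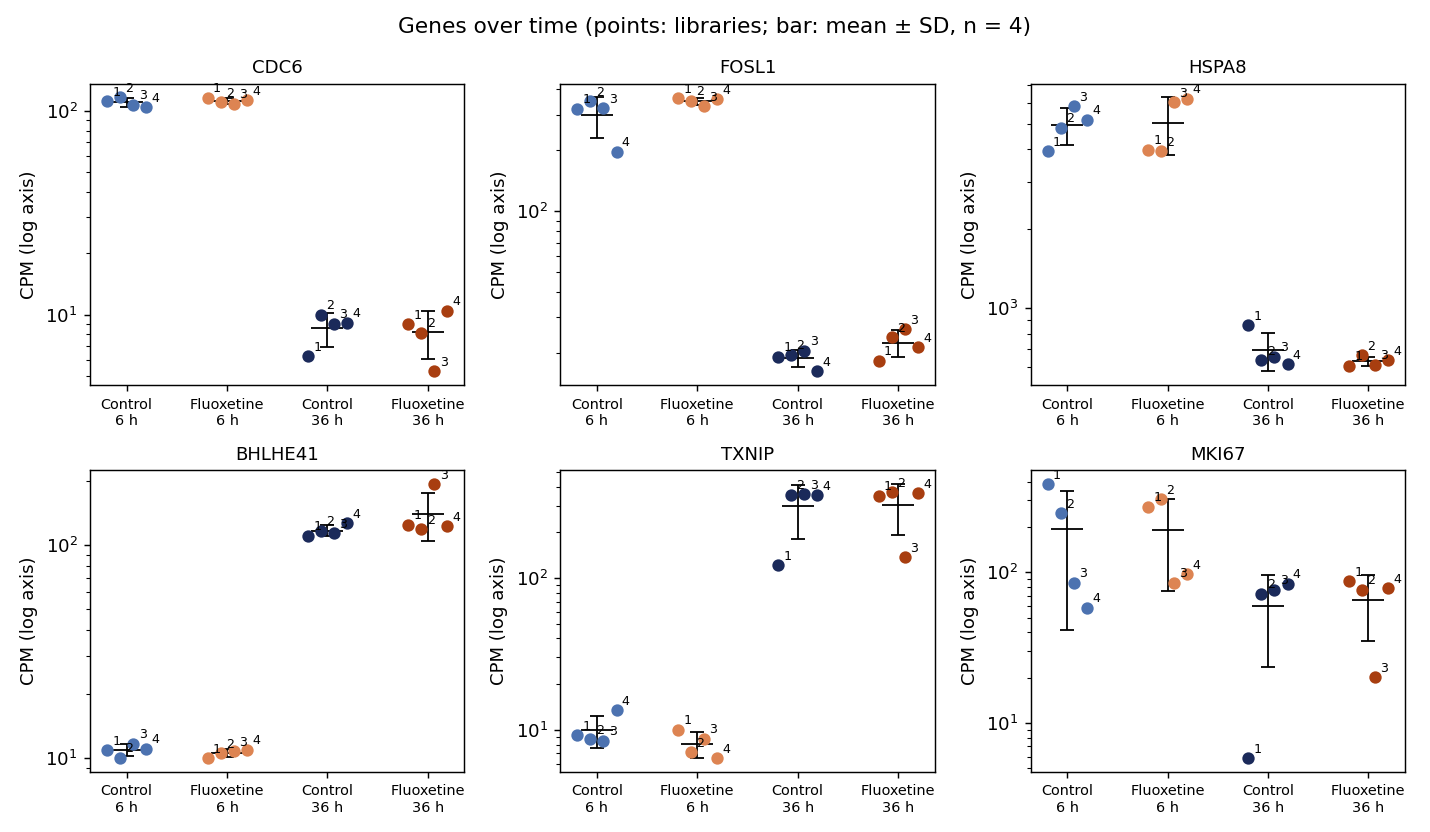
CPM on a log axis of CDC6, FOSL1, HSPA8, BHLHE41, TXNIP and MKI67 in each library, with points numbered by replicate and bars showing mean ± SD of 4 libraries per group. CDC6 averaged 110 and 112 CPM at 6 h and 8.60 and 8.21 CPM at 36 h in control and exposed cells, and MKI67 ranged widely at both times.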

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

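All tests of explanations in this part, with their bounds, were chosen after the results were seen. A library was picked out where its gap to the nearest library of its group of 4 was too large a share of the group's range for a 95% test (Dixon's). Among 464 groups of values tested, 94 held such a library, where chance marks about 1 in 20 independent groups, or 23.2 here. These groups are not independent, as they share the 16 libraries and many genes were picked by their results. Of the genes marked, 42 were in control replicate 1 and 35 in fluoxetine replicate 3, both at 36 h. The 94 therefore mostly reflect few libraries.

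Control replicate 1 at 36 h stood apart in 4 library measures. Ribosomal protein genes took 17.05% of its counts, the 50 most abundant genes 21.6% and long genes 24.86%, and its endothelial markers summed to 12.4 CPM. It was above its group for RRP12 (79.1 CPM), ACTB (4040), SH2D3C (20.7), BBC3 (115), DBP (167), CCL2 (213), HSPA8 (863), SOD2 (706), RPL24 (2090), OPTN (471), FST (26.9), ATP5MC2 (532), IFI44 (95.1), IFITM3 (1520), RPL10 (3050), HEATR3 (18.1), HIST1H2BD (126), BTG2 (255), SQSTM1 (1080), IVL (31.5), LSM6 (17.7), NDUFB8 (17), RPS9 (5360), CYCS (213), NDUFA11 (46.8), TCIM (37.4), ULK1 (184), AMTN (218), EIF4EBP1 (139), OSER1-DT (29.1), TMA7 (13) and HIST1H3H (20.3). It was below its group for SNCAIP (2.85 CPM), THBS1 (32.3), MKI67 (5.86), TPM4 (224), RRM2 (1.46), CIITA (2.24), SS18L1 (16.3), SERPINB2 (5.71), OR2I1P (11.3) and TXNIP (122).

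Fluoxetine replicate 3 at 36 h had 5.822% ribosomal protein counts, below its group, and 85.7 CPM of summed fibroblast markers, above it. It was above its group for TG (77.1 CPM), ACTB (3100), SH2D3C (38.2), BMF (149), SOD2 (548), HMGCS1 (104), ADAM23 (27.4), BHLHE41 (193), WDR19 (38.5), BTG2 (282), SQSTM1 (1330), ATF3 (50.9), TP53INP1 (132), ISLR2 (32.2), TCIM (28.5), ULK1 (298), AMTN (133) and OSER1-DT (11.6). It was below its group for HSPA5 (348 CPM), SNCAIP (6.46), NFKBIA (144), ATP5F1B (571), HSPD1 (182), RPL10 (1180), MKI67 (20.1), GJB2 (3.51), RPS9 (897), RRM2 (0.237), CYCS (92.1), PKP3 (227), KRT14 (175), SERPINB2 (7.74), TAPBP (574), OR2I1P (16.9) and TXNIP (138).

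In other libraries, control replicate 4 at 6 h stood apart for BNIP3L (35.8 CPM), ATP5MC2 (318), TCIM (0.583) and TXNIP (13.5), and control replicate 2 at 36 h for PKP3 (434). Fluoxetine replicate 2 at 6 h stood apart for LYAR (70.9 CPM), and replicate 4 at 6 h for ARSB (18.1) and immune markers (7.83). At 36 h fluoxetine replicate 2 had 22.52 megacounts, the most of its group, and fluoxetine replicate 4 stood apart for SPCS2P4 (7.08 CPM) and SPRR2A (0.34). Camera with a preset correlation called a difference of the exposure effect between the times for oxidative phosphorylation (-0.513), mitochondrially encoded (0.237), ribosomal protein (-0.466), ribosome biogenesis (-0.0768) and interferon-stimulated genes (0.106). All 5 calls were lost, at an adjusted p = 0.952 with an estimated correlation, and fry (smallest adjusted p 0.977) and the fit without the 3 libraries that stand apart gave 0 lists.

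The lower level of 148 ribosomal protein and oxidative phosphorylation genes with fluoxetine at 36 h may come in large part from control replicate 1. Measured here as the difference of mean log2 CPM, its median was -0.534, smaller in size than the medians of edgeR's fit given above. Without that library the median was -0.128. As a mean over the same libraries, the 4 exposed libraries lay -0.139 ± 0.116 (SE) from control replicates 2 to 4. With control replicate 1 set aside, this argues against an exposure effect of the whole size seen by this measure. Control replicate 1 was set aside because its ribosomal protein share was seen to be high, so the smaller difference is no separate test. Removing each library's trend on gene length left -0.354 (interquartile range -0.51 to -0.206), which argues against that trend as the whole cause. What set control replicate 1 apart stays open. Without it both lists still passed camera's preset test (adjusted p = 6.1e-07 and 4.47e-08). The remainder may come in part from fluoxetine replicate 3, which lay below its group by medians of -0.415 (ribosomal protein) and -0.367 (oxidative phosphorylation). Without the 3 libraries that stand apart neither list passed, as given above. These libraries were picked after the values were seen, and a smaller effect of the exposure is not excluded.

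At 6 h 603 genes differed between replicates 3 and 4 and replicates 1 and 2 (295 higher and 308 lower), with interferon-stimulated genes higher in replicates 3 and 4 by a median log2 difference of 1.91 in exposed cells. In unexposed controls the difference was 1.16, which argues against the exposure. In exposed cells the difference correlated at 0.0424 with the time effect in controls, and G1/S genes differed by -0.0877 (-2.12 with time). These values argue against a step along the whole course from 6 h to 36 h. G2/M genes went with such a step, at -1.23 against -1.69 with time by the same measure. A shorter delay near 6 h was not tested. Immune markers differed by 1.72 CPM (6.15 ± 0.872 and 7.87 ± 1.44 SD), mostly CD14 (5.6 and 7.15), and with the other markers under the floor immune cells stay open. A batch shared by the exposed and control cultures may account for it, since the difference correlated across genes at 0.644 between treatments. The labels name no batch, and genes are not independent replicates.

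Control replicate 2 at 6 h lay between these pairs of replicates. It may hold a mixture of material of both kinds. On the linear scale, where a mixture places all genes at the same share of the way, genes higher and lower in replicates 3 and 4 lay at 0.384 and 0.348, a difference of 0.036 ± 0.015 (SE). On the log2 scale they lay at 0.524 and 0.247, a difference of 0.277 ± 0.016 (SE), which argues against 1 culture in which every gene had moved the same share of its log2 difference. Both SEs are taken over genes of this library that were picked for differing between the pairs. Genes are not independent replicates, so the SEs may be too small. No biological explanation was tested.

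Other splits of the same libraries were counted for each result, with the real split included. Where the real count was 0 genes, every split gives as many by construction, which leaves chance open and holds for fluoxetine at 6 h (35 of 35, highest other 800), at 36 h (35 of 35, highest other 0) and for the difference between the effects (100 of 100 drawn splits, highest other 608). For lists at 6 h chance was not excluded (4; 33 of 35, highest other 14). The split with 800 genes parts replicates 1 and 2 from 3 and 4, which points to that structure, and the 8 splits that part all 4 numbered pairs gave at most 0. At 36 h chance was not excluded for lists (3; 33 of 35, highest other 18). With time no other split gave as many genes in control (7696 genes, 1 of 35, highest other 3768) or in exposed cells (8106 genes, 1 of 35, highest other 0). This argues against a chance split of these libraries, and 1 of 35 is the smallest share possible here. The labels do not say whether replicates are separate cultures, so chance differences between cultures are not excluded. For lists with time the counts were 15 in control (14 of 35, highest other 19) and 12 in exposed cells (27 of 35, highest other 18). Splits that leave most libraries of a time together keep part of the time difference, so these list counts cannot decide on chance. For the difference between the effects chance was not excluded for lists (5; 81 of 100, highest other 18). With quality weights the 2384 genes at 6 h were matched by 17 of 35 splits, with up to 7039 genes, so chance was not excluded. Among the 8 splits that part all 4 numbered pairs the highest count with quality weights was 4381.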

How the results depend on the processing

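Besides settings that leave out 1 library, named genes kept their direction and side of the threshold in 1114 cases (a gene in 1 comparison under 1 setting), turned in 20, newly passed in 10 and no longer passed in 5. Counts and correlations were about as reported in 87 cases, moved in 23 and turned in 1. The cause of the changes below was not tested. Quality weights, the added term, and settings that leave out more than 1 library were chosen after seeing the data. With quality weights limma-voom called 2384 genes for fluoxetine at 6 h, 2 at 36 h, 12611 with time in control and 355 for the difference of effects. With 4 libraries left out and a term for the 6 h replicates, 1 gene passed at 36 h.

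With an estimated correlation 0 lists passed in each of the 5 comparisons. Without the 3 libraries that stand apart 0 lists passed for both exposures and their difference, and with an estimated correlation as well 0 did so, against 1 in each time comparison. The rotation test fry gave 0 lists for both exposures and their difference, 18 with time in control and 19 with time in exposed cells. The correlation of the exposure effects was 0.644 with the strict filter and -0.0099 without the 3 libraries. Leaving out single libraries gave 0 to 9 lists at 6 h, 3 to 14 at 36 h and 3 to 10 for the difference, and correlations of 0.00915 to 0.357.

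In the exposure comparisons, where none of the genes named by the rule passed in edgeR's main test, some fitted log2 fold changes turned. Without the 3 libraries, and with the 4 left out and the term, they were at 6 h 0.132 and 0.0911 for IFI44, 0.0618 and 0.0329 for KRT14, 0.0972 and 0.0904 for KRT10, 0.199 and 0.0991 for IVL and 0.138 and 0.14 for KRT6A. At 36 h they were 0.0133 and 0.0119 for EIF4EBP1, 0.0925 and 0.0921 for IVL and -0.0629 and -0.0618 for HMGCS1. With limma-voom at 6 h MKI67 had 0.144 and IVL 0.0174. Leaving out single libraries gave at 6 h -0.662 to 0.135 for IFI44, -0.358 to 0.545 for MKI67, -0.32 to 0.0703 for KRT14, -0.301 to 0.105 for KRT10, -0.147 to 0.206 for IVL and -0.279 to 0.257 for KRT6A. At 36 h it gave -0.244 to 0.432 for MKI67, -0.302 to 0.104 for KRT10, -0.407 to 0.0976 for IVL, -0.0809 to 0.288 for KRT6A, -0.0862 to 0.224 for HMGCS1 and -0.138 to 0.309 for SQSTM1.

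With the replicate number as a block 0 genes passed for either exposure or the difference, 7231 changed with time in control and 7842 in exposed cells, the correlation was 0.303, and MKI67 had 0.00939 at 6 h and -0.199 at 36 h. Joined to the fit of 8 libraries the block also gave 0 genes at 6 h. At 6 h, where all same-numbered correlations were over 0.1, the block changed no call. Even there, of the control libraries only replicate 2 correlated best with its own number. Same-numbered libraries' deviations correlated at -0.342, 0.226, -0.295 and 0.103 at 36 h, at -0.38, 0.222, 0.041 and -0.496 between times in control and at 0.0292, 0.0211, 0.0659 and -0.125 in exposed cells, and not every library correlated best with its own number. With time in control AMTN lost its call with the block (edgeR adjusted p of 0.195), limma-voom (0.344), the fit of 8 libraries (0.0529) and without the 3 libraries (0.459), and DESeq2 gave it no adjusted p. The 10 newly passing cases were of MKI67 and IVL in the 2 time comparisons.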

Other observations

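The tests in this part were chosen after the values were seen. Of 30 listed serotonin genes 10 were tested, and some of them changed with time. MAOA, which degrades serotonin, rose from 34.3 to 81.7 CPM in control cells (log2 1.07 ± 0.218 SE; edgeR adjusted p = 0.000902) and from 35.2 to 93.1 CPM in exposed cells (1.19 ± 0.218; edgeR adjusted p = 0.00034). HTR1D, a serotonin receptor, fell from 4.66 to 1.35 CPM (edgeR adjusted p = 0.00603) and from 5.40 to 1.49 CPM (edgeR adjusted p = 0.00232). These genes were named outside the rule for named genes.

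At 6 h replicates 3 and 4 were also compared with replicates 1 and 2 by list, over both treatments, where 1.89% of all genes were higher and 1.97% lower. Of 50 G2/M genes 14 were lower and 0 higher (median -1.13; camera's preset adjusted p = 9.73e-20; adjusted p = 0.319 with an estimated correlation), while of 50 G1/S genes 1 was higher (median -0.0643). Of 19 heat shock genes 8 were higher and 0 lower (median 0.593; preset adjusted p = 6.64e-13; adjusted p = 0.162 with an estimated correlation). Of 33 wound-edge genes 9 were higher and 1 lower (median 0.803; preset adjusted p = 6.14e-05; adjusted p = 0.0309 with an estimated correlation), and that list and the interferon-stimulated genes (0.0309) were the only ones to pass with both. The comparison was drawn after the values were seen.

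At 36 h control replicate 1 and fluoxetine replicate 3 departed from the other libraries of their groups in part alike. Across 10853 genes, which are not independent replicates, their departures correlated at r = 0.351 (Spearman's rho 0.204). Of 345 genes more than 1 log2 unit higher in fluoxetine replicate 3, 310 (89.9%) were also higher in control replicate 1, where 46.6% of all genes were higher. Of 332 genes more than 1 log2 unit lower, 308 (92.8%) were also lower. Both libraries were higher for NRF2 target (medians 1.35 and 1.16) and cholesterol genes (1.35 and 0.842) and lower for G1/S (-0.807 and -0.789) and G2/M genes (-1.28 and -1.36). Their medians had opposite signs for ribosomal protein (1.62 and -0.415), oxidative phosphorylation (1.49 and -0.367), mitochondrially encoded (-0.972 and 0.274), extracellular matrix (-0.273 and 0.721) and antigen presentation genes (0.284 and -0.604), among others. The lists given were picked after the values were seen. No explanation was tested.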
